A study of Macaca mulatta with 2 samples.

How the data were processed

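Placenta of the rhesus macaque (Macaca mulatta) was profiled by RNA sequencing in 2 libraries. Per the labels, placental tissue was taken at caesarean section and frozen, total RNA was purified on columns with a DNase step, and polyadenylated RNA was made into strand-specific libraries read as 75 bp paired ends. Reads were trimmed with Trim Galore 0.6.4 and quantified with RSEM 1.3.2 against the genome build Mmul_10, per the submitters' processing notes. The aligner and the annotation release are not given in the sources used here. RSEM shares a read that fits several genes between them by likelihood, so values of near-identical gene copies are uncertain.

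Per the file headers, each library had its own RSEM gene table with 34884 Ensembl gene identifiers, and the libraries were not pooled. The expected counts are RSEM's estimated read counts per gene, not normalized by the authors. They were whole numbers for 70.3% of genes in replicate 1 and 66.4% in replicate 2. The TPM values (transcripts per 1000000) were computed by the authors from those counts and each gene's effective length, and they had the same sum in each library. The deposited FPKM values (fragments by transcript length and library size) carry the same information on another scale and served as an alternative here. RSEM's posterior mean TPM and posterior standard deviation of the count, deposited in the same tables, were used as an alternative and as a measure of shared reads. Because TPM divides by effective length, 1 read on a very short transcript gives a high TPM.

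Gene symbols were taken from a table of gene identifiers and symbols, which named 24022 of the 34884 identifiers (68.9%). The other 10862 are given by identifier or as a total. Identifiers with the same symbol were summed, which concerned 95 symbols and 6106 identifiers and left 28873 genes. Of these, Metazoa_SRP alone held 3385 identifiers. Counts of genes and the correlation between libraries were computed on identifiers, and lists and named genes on symbols. No genome or annotation of the build was used, so no coordinates are given and GC content was not examined.

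The labels give 1 group of 2 libraries, numbered 1 and 2 in their titles, and no second group. No difference between groups could therefore be tested, and levels are given as mean ± SD over the 2 libraries (n = 2). The labels speak of 2 placenta samples but do not say whether they came from separate animals, so the spread may be technical. The total expected count was 7748724 in replicate 1 and 13633797 in replicate 2, so low values in replicate 1 are the less precise ones. A chi-square test of the rounded expected counts, over genes with at least 20 counts in sum, asked whether both files hold 1 library. Agreement was measured by Pearson's r and Spearman's rho of log2(TPM + 1) across genes, which are not independent replicates. The spread was also given as the biological coefficient of variation from edgeR 4.0.16 (common dispersion, TMM scaling, its default filter on low counts, expected counts rounded). DESeq2 1.42.0 served as an alternative. Other steps used R 4.3.3 and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

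Genes that differed 2-fold between the libraries were those with a log2 ratio of TPM + 1 (replicate 2 over replicate 1) of at least 1 in size, among genes with a mean TPM of at least 5. The pseudocount of 1 understates ratios of low genes. Folds with an interval use expected counts over TMM library sizes, with exact Clopper-Pearson 95% intervals. Where 1 library held no read, a floor of 3 counts gave a lower bound. These intervals and bounds cover counting error only, since reads are not independent molecules.

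The level of each of 31 gene lists, fixed before the data were examined, was the median of its members' mean TPM. Its percentile was taken among 10000 random lists of the same size drawn from genes with a mean TPM of at least 0.1. List members under that minimum were kept. The difference of a list between the libraries was the median log2 ratio of its members with a mean TPM of at least 1, where at least 5 had one. Its percentile was taken among 10000 random lists matched on mean TPM in 20 bins. A list stood apart when it lay outside the central 99%. Members of a list are often co-regulated, so these percentiles describe the libraries and are not p-values.

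The genes named were set by a rule fixed before the data were examined. The rule covered the 25 genes with the highest mean TPM, the 4 highest members of each list and the 10 genes with the largest ratios in each direction. It also covered a set of 16 placental and control genes. Not every gene under the rule is given below. At most 4 genes without a symbol were to be named by identifier. Of the 16, PEG10, MAMU-AG and XIST had no row under that symbol. CSH3, INHA, CYP11A1, HSD17B1, CRHR1, ITGA6, CGB8, EGR1, POSTN and the genes of the closing section were named outside the rule, after their values were seen.

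The method was tested on simulated counts for the comparison of library 2 with library 1, over 34884 genes. A biological coefficient of variation of 0.3 was recovered as 0.324. Of 100 genes changed 4-fold 92% were recovered, and of 100 changed 8-fold 100%. These rates are for simulated counts and cannot be carried over to the 2-fold rule on TPM + 1, above all for genes with few reads. That rule set no minimum of reads, and 328 of its 833 genes were under 200 bases long with under 50 reads. No rate of unchanged genes called 2-fold different was obtained. None (0%) of 100 unchanged lists stood apart. Those lists were random draws of independently simulated genes, much like the lists they were compared with, so a low rate was built in. It gives no error rate for the fixed lists, whose members are often co-regulated. Alternatives covered the pseudocount, the filter on low values, the scaling, FPKM or count units, mitochondrial genes, same-symbol identifiers and each library left out.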

Results

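The placental transcriptome of the rhesus macaque was measured by polyadenylated RNA sequencing in 2 libraries of placenta collected at caesarean section. The labels put both in 1 group, so the data answer which genes the tissue expressed, at what level, and how far the libraries agreed. Replicate 1 held 7748724 expected counts and replicate 2 held 13633797, a ratio of 1.76. At least 1 TPM was reached by 16287 genes in replicate 1, by 16721 in replicate 2 and by 15125 in both. Values are TPM, as mean ± SD over the 2 libraries (n = 2) unless a value per library is given.

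A few placental genes made up much of the transcriptome. The growth hormone variant gene GHV (ENSMMUG00000039847), a pituitary growth hormone relative expressed by trophoblast, was the most abundant at 133695 ± 5126 TPM, or 13.4% of all TPM. The placental lactogen genes CSH2 (ENSMMUG00000023707) and CSH4 (ENSMMUG00000023706) followed at 67053 ± 2461 and 33787 ± 16885. CSH4 differed between the libraries, at 21848 in replicate 1 and 45726 in replicate 2. Together with CSH3 at 475 ± 157, these genes took 23.5% ± 2.46 of all TPM. CSH2 shares reads with an unnamed gene, ENSMMUG00000000578 (16585 ± 4218). In replicate 1 the posterior standard deviation was 5752 of 227788 counts for CSH2 and 5751 of 57487 for the unnamed gene, so the split between them is uncertain.

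The 10 most abundant identifiers took 38.9% ± 1.68 of all TPM and the 100 most abundant 61.0% ± 1.47, before identifiers of the same symbol were summed. Several of the 10 had no symbol, so what they encode is not known here. Among genes with a symbol, SERPINE2, an inhibitor of serine proteases, stood at 16746 ± 916. WFDC2, a secreted protein with a whey acidic protein domain, stood at 8830 ± 1147, the growth factor gene IGF2 at 7861 ± 261 and the extracellular matrix gene FBLN1 at 5279 ± 1596. INSL4, a placental member of the insulin and relaxin family, reached 5001 ± 43.1, and B2M, the light chain of MHC class I, 4045 ± 662. The 13 mitochondrially encoded genes took 7.44% ± 0.869, led by COX2 at 15188 ± 1774 and COX1 at 12892 ± 3096. Genes without a symbol took 22.6% ± 0.785, and the most abundant of them, ENSMMUG00000011358, reached 30831 ± 8965. Metazoa_SRP, a signal recognition particle RNA family summed over 3385 identifiers, stood at 19452 ± 2433. The posterior standard deviations of its identifiers added up to 26.5% of its count in replicate 1. This sum is an upper limit for the standard deviation of the total, which was not computed.

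**Figure D1:**
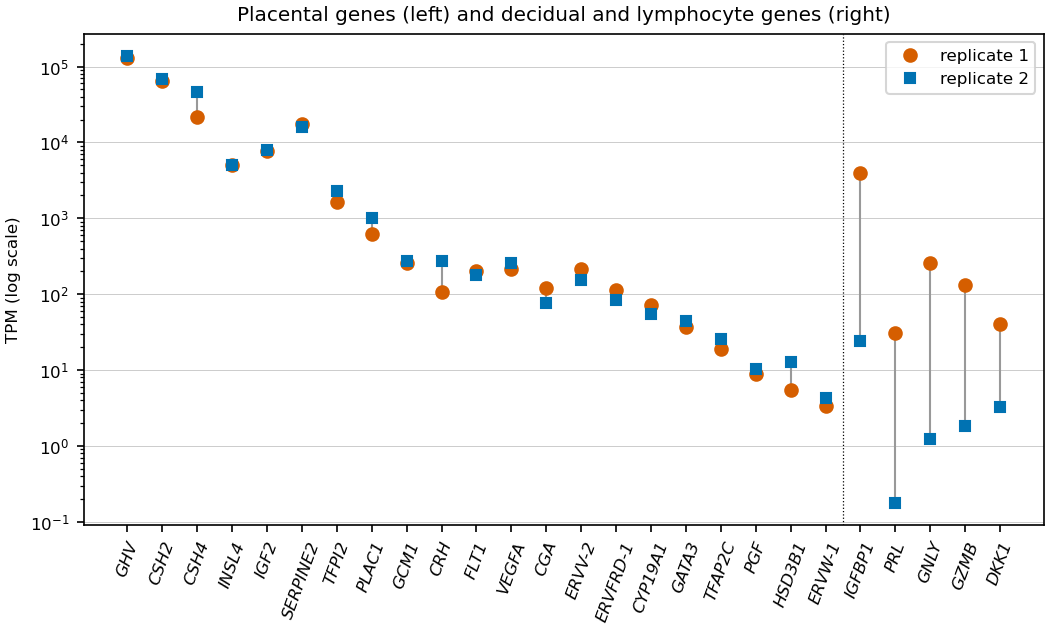
TPM (log axis) of 26 genes in replicate 1 (circles) and replicate 2 (squares), with a line joining the 2 libraries. Left of the dotted line are placental genes, from GHV near 133695 TPM to ERVW-1 near 3.81, and right of it are decidual and lymphocyte genes, such as IGFBP1 at 3982 and 24.1, which were far higher in replicate 1.

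Hormone and steroid genes were expressed far above random genes. The median of the 20 measured members of the hormone and steroidogenesis list was 79.7 TPM, above all 10000 random lists (percentile 100), and 18 of them reached 1 TPM in both libraries. ADM, the vasodilator adrenomedullin, stood at 947 ± 51.1 and the inhibin subunit gene INHA at 152 ± 11. CGA, the alpha subunit of the glycoprotein hormones, stood at 97.3 ± 30.7. The only chorionic gonadotropin beta gene with a row under its symbol, CGB8, held 3 reads in replicate 1 and 0 in replicate 2. The side-chain cleavage gene CYP11A1 stood at 75.3 ± 1.77, aromatase CYP19A1 at 63.8 ± 11.7 and HSD3B1, which makes progesterone, at 9.20 ± 5.28. CRH (ENSMMUG00000021587), the corticotropin-releasing hormone, differed between the libraries, at 108 and 272 TPM. Its count fold was 2.55 in favour of replicate 2 (95% interval 2.24 to 2.91, counting error only). HSD17B1, which activates estrogens, was likewise 2.22-fold higher there (1.86 to 2.65). Of the 18 members with a mean of at least 1 TPM, 5 were at least 2-fold higher in replicate 2, CSH4 and HSD3B1 among them, and 0 were 2-fold lower. In the CRH and glucocorticoid list (15 members, median 7.68 TPM, percentile 76.4), the cortisol enzymes HSD11B1 and HSD11B2 stood at 163 ± 49.3 and 136 ± 65.4, and TSC22D3, a glucocorticoid target, at 72.8 ± 10.1. The receptor gene CRHR1 had a TPM of 0 in both libraries.

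Trophoblast genes were prominent in both libraries. Syncytiotrophoblast markers had a median of 80.9 TPM (20 members, percentile 100), with the protease inhibitor TFPI2 at 1971 ± 498, the cytokine GDF15 at 1140 ± 27.9, CAPN6 at 874 ± 3.06 and PLAC1 at 817 ± 265. Cytotrophoblast markers had a median of 40.3 (16 members, percentile 100), led by the keratin KRT18 at 284 ± 7.79, PAGE4 at 203 ± 2.11 and VGLL1 at 107 ± 13.8. Extravillous markers had a median of 40.5 (14 members, percentile 100), led by fibronectin FN1 at 1964 ± 619, PLAC8 at 360 ± 7.50 and SERPINE1 at 346 ± 226. SERPINE1 stood at 505 in replicate 1 and 186 in replicate 2, and which cells expressed the markers of these lists was not tested. The trophoblast transcription factors had a lower median of 17.5 TPM (25 members, percentile 99.65). It lay inside the central 99% against genes of at least 1 TPM (percentile 96.81), with TMM-normalised CPM (97.515) and without replicate 2 (99.435). GCM1, which drives syncytial fusion, stood at 264 ± 9.04 and TBX3 at 174 ± 1.39, MAFK at 144 ± 11.6 and TFAP2A at 91.8 ± 6.99. GATA3 stood at 40.4 ± 5.30 and TFAP2C at 22.3 ± 4.72.

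Envelope genes of retroviral origin, which in humans include the fusogenic syncytins, were detected in both libraries. ERVV-2 reached 185 ± 45.9, ERVV-1 104 ± 4.36, ERVFRD-1 (syncytin-2) 98.8 ± 22.3 and MFSD2A, the syncytin-2 receptor, 57.8 ± 18.8. ERVW-1, the human syncytin-1 gene, stood at 3.81 ± 0.643, and whether its macaque copy encodes a functional protein was not tested. The whole fusion and retroelement list of 17 members had a median of 6.13 TPM and did not stand apart from random lists (percentile 65.3).

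Imprinted genes, of which mainly the copy of a single parent is active, had a median of 36.6 TPM (27 members, percentile 100). After IGF2 and TFPI2 the highest were the growth restrainer CDKN1C at 680 ± 113 and the hydrolase-family gene MEST at 534 ± 41. The insulin-like growth factor list had a median of 33.8 (16 members, percentile 99.98), with the binding protein IGFBP3 at 1422 ± 161 and the protease PAPPA at 328 ± 89.5. Without replicate 1 its percentile was 99.46, inside the central 99%. Nutrient and drug transporters had a median of 29.6 (42 members, percentile 100), led by the calcium-binding S100P at 917 ± 31.5, the glucose transporter SLC2A1 at 669 ± 74.2, the fatty acid carrier CD36 at 261 ± 11.7 and FABP5 at 231 ± 44.8. Angiogenic genes had a median of 11.6 (15 members, percentile 92.3). Among them VEGFA stood at 237 ± 34.2, ENG at 204 ± 34.2 and FLT1, whose soluble form binds VEGF, at 191 ± 16.1, while PGF was at 9.70 ± 1.05. Hypoxia-response genes had a median of 8.22 (15 members, percentile 79.1), with NDRG1 at 173 ± 17.2.

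Over all lists, 14 of 30 lay above the central 99% of random lists and 2 below, with 10 above without replicate 1 and 13 without replicate 2. The medians of the 2 below were under the 0.1 TPM minimum of the random genes. Their percentile of 0 was therefore fixed by that minimum. The number above was 12 with TMM-normalised CPM and 10 against random genes of at least 1 TPM. In these settings the endometrial gland list also lay below (percentiles 0.09 and 0). Its median of 0.535 TPM was under the 1 TPM minimum, so the 0 was fixed by that minimum. The erythroid list lay below only against genes of at least 1 TPM (0.4), where its members under 1 TPM were kept. Markers of other cell types were present at unequal levels. Stromal fibroblast genes had a median of 113 TPM (17 members, percentile 100), including COL3A1 at 262 ± 38.1, DCN at 201 ± 15.7 and VIM at 196 ± 113. Macrophage genes had a median of 24.0 (16 members, percentile 99.85), led by C1QA at 83.6 ± 1.27 and the receptor CSF1R at 38.6 ± 1.08. The percentile was 99.16 without replicate 1 and 98.98 against genes of at least 1 TPM, both inside the central 99%. Immune tolerance and complement genes had a median of 18.1 (22 members, percentile 99.82), with CD59 at 634 ± 66, MAMU-E at 629 ± 41.8 and CD55 at 240 ± 156, and percentiles of 96.915 without replicate 1 and 97.13 against genes of at least 1 TPM. Fetal endothelium had a median of 12.6 (16 members, percentile 95.5), with PECAM1 at 389 ± 181. Smooth muscle and pericytes had a median of 12.8 (12 members, percentile 93.1), with TAGLN at 112 ± 5.19, and amnion epithelium 4.42 (5 members, percentile 47.1), with SFN at 19.8 ± 6.35.

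Proliferation genes had a median of 6.76 TPM (14 members, percentile 69.3), with CDK1 at 9.70 ± 0.764. Interferon-response genes had a median of 4.66 (14 members, percentile 46.3), with IFI27 at 281 ± 245 and IFI6 at 165 ± 35.9. Inflammation and labour genes had a median of 12.9 (14 members, percentile 94.9), with the gap junction gene GJA1 at 181 ± 23.3 and the decoy receptor IL1R2 at 146 ± 39.5. Ribosomal proteins (median 453, 17 members) and the 13 mitochondrial genes (median 4442) lay at percentile 100. Liver, brain and heart markers had a median of 0.04 (13 members, percentile 0), where the cardiac troponin gene TNNT2 at 26.2 ± 8.58 was the exception. The 11 Y-linked genes had a median of 0 (percentile 0). Both medians were under the 0.1 TPM minimum of the random genes, which alone sets these percentiles to 0. DDX3Y held 0 reads in replicate 1 and 1 in replicate 2, and RPS4Y2 stood at 3.12 and 2.49 TPM.

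**Figure D2:**
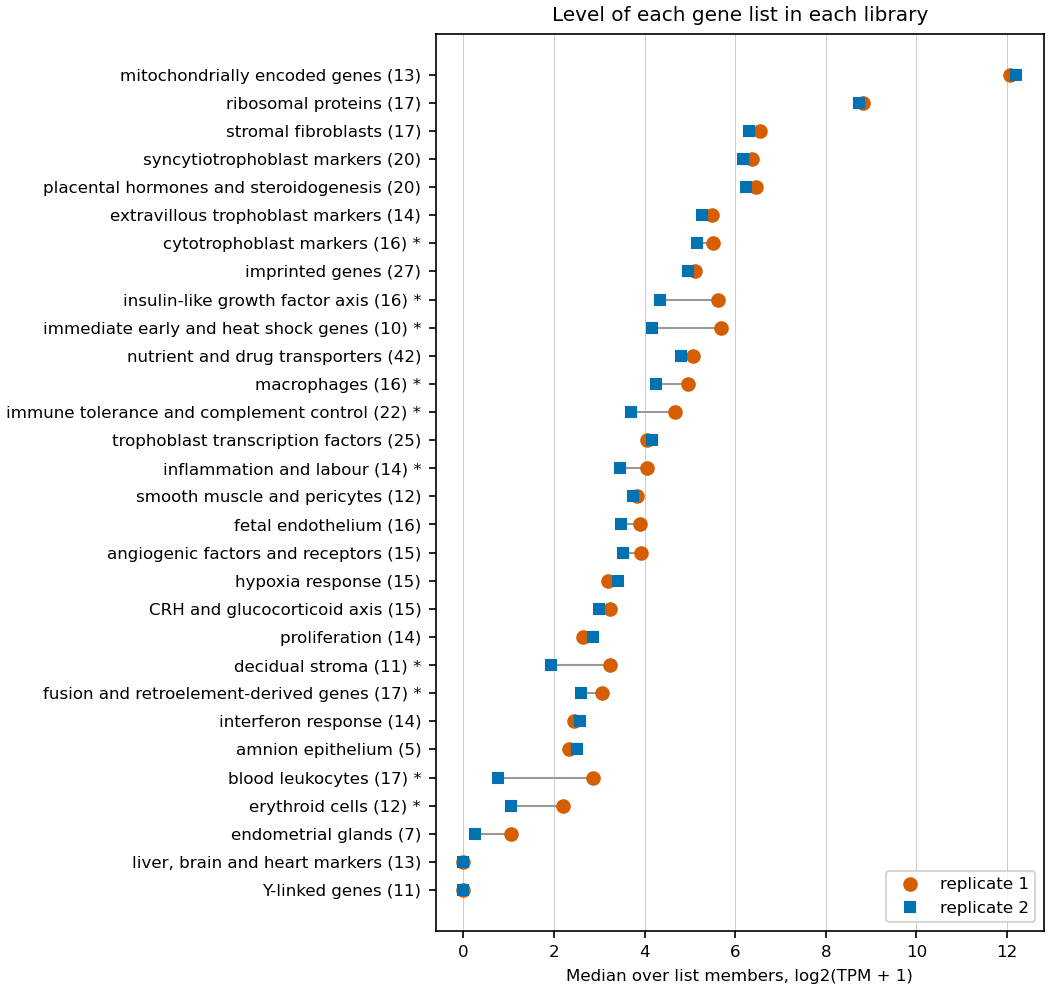
Median over the members of each gene list, as log2(TPM + 1), in replicate 1 (circles) and replicate 2 (squares), with the number of members in parentheses and an asterisk where the list stood apart between the libraries. The 10 marked lists were all lower in replicate 2, with blood leukocytes at a median of 6.26 TPM in replicate 1 and 0.69 in replicate 2.

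The libraries differed little over most genes. Pearson's r of log2(TPM + 1) was 0.954 and Spearman's rho 0.915 over 34884 genes. Among the 10715 genes with a mean TPM of at least 5, the median log2 ratio of replicate 2 over replicate 1 was -0.03, its quartiles were -0.27 and 0.22, and 82.3% of the genes lay within 1.5-fold. The biological coefficient of variation (edgeR) was 0.248 over 14995 genes. The counts differed by far more than sampling noise, at a chi-square of 48.3 per degree of freedom over 16110 genes, so the files do not hold the same library. Of the 10715 genes, 833 (7.77%) differed at least 2-fold, 418 higher in replicate 1 and 415 higher in replicate 2. The count and its balance depended on the setting. With TMM-normalised CPM in place of TPM, 278 were higher in replicate 1 and 197 in replicate 2 (475 in all), and with CPM by DESeq2's size factors 282 and 197 (479). These change the unit and the scaling together, so the shift is not put down to either. With conditions chosen after the data were seen, the numbers were 288 and 183 (471) for genes with 50 reads and 304 and 195 (499) for genes of at least 200 bases. With no filter the balance leaned the other way, at 1097 and 1427. With 1 library on each side, no such difference has a replicate check.

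The genes with the largest excess in replicate 1 included products of decidua, the maternal lining of the uterus, and of cytotoxic lymphocytes. IGFBP1 (ENSMMUG00000059330), a secreted product of decidualised stroma, stood at 3982 TPM in replicate 1 and 24.1 in replicate 2, a count fold of 163 (95% interval 154 to 172). The kallikrein protease gene KLK3 stood at 1566 and 13.9 TPM, a fold of 111 (96.8 to 128). The cytotoxic granule genes GNLY and GZMA were 110-fold (62.3 to 213) and 136-fold (77.4 to 264) higher in replicate 1. The immunoglobulin light chain IGKC held 254 reads in replicate 1 and 1 in replicate 2, a fold of 461 (81.9 to 18267). SCGB1A1, a secretoglobin, held 73 and 0 reads, which makes it at least 44.1-fold higher against the floor of 3 counts, with a lower limit of the exact 95% interval of 35.0. ECRG4 and the protease inhibitor SERPINA3 were both 124-fold higher (59.9 to 311 and 75.9 to 217). The unnamed ENSMMUG00000055814 held 113 and 0 reads, at least 68.3-fold higher against that floor, with a lower limit of 54.7. PRL, prolactin, held 97 reads in replicate 1 and 1 in replicate 2 (176-fold, 30.8 to 7020).

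The largest ratios in the other direction rested mostly on few reads. Of the 10 genes, 8 had no read in replicate 1 and 1 to 4 reads in replicate 2, among them the small nucleolar RNAs SNORD38A, SNORD36, SNORD29, SNORD49B and SNORD102 and the microRNA gene mml-mir-1234. SNORD38A stood at 160 TPM from 2 reads and SNORD29 at 103 TPM from 1 read. No difference was detectable for these genes at this depth. ENSMMUG00000064501 held 0 and 401 reads, but its posterior standard deviation was 11.9 reads in replicate 1 and 65.2 in replicate 2, as for genes that share reads, so no fold is given.

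**Figure D3:**
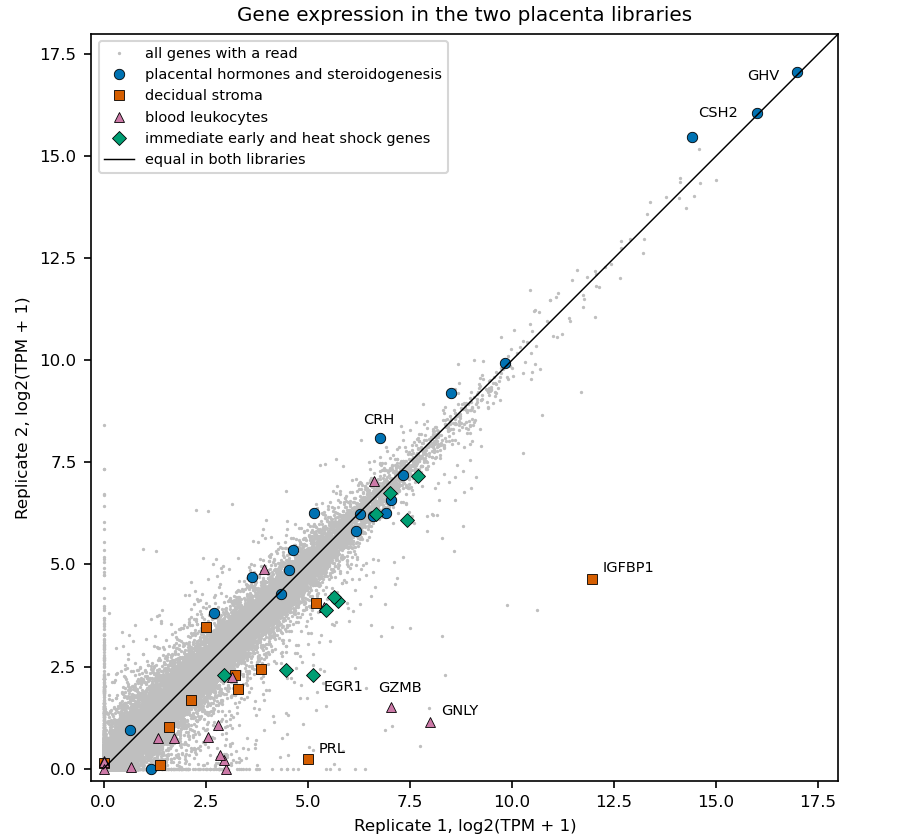
Expression of each gene in replicate 1 (horizontal) and replicate 2 (vertical), both as log2(TPM + 1). Grey points are all genes with a read, coloured symbols are members of 4 gene lists and the line marks equal values. The median log2 ratio of the hormone genes was 0.09, with 5 of 18 at least 2-fold higher in replicate 2, such as CRH, while decidual and leukocyte genes such as IGFBP1, PRL, GNLY and GZMB lie below it.

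Of 27 gene lists with enough members, 10 stood apart between the libraries, all of them lower in replicate 2, where 0.27 would do so by chance for independent genes. Blood leukocyte genes had a median of 3.42 TPM over both libraries (percentile 30.2), with 6.26 in replicate 1 and 0.69 in replicate 2. They had the lowest median log2 ratio, -1.74, with 11 of 13 members lower in replicate 2 and 8 of them at least 2-fold. GZMB stood at 131 and 1.86 TPM and S100A9 at 41.4 and 14.6, whereas the granulocyte receptor gene CSF3R stood at 97.3 and 130. Decidual stroma genes had a median of 6.15 TPM (percentile 62.7), with 8.38 in replicate 1 and 2.83 in replicate 2. Their median log2 ratio was -1.15, with 8 of 9 lower and 5 at least 2-fold, such as HAND2 at 35.9 and 15.6 TPM and FOXO1 at 13.5 and 4.46. Endometrial gland genes (0.535 TPM, 7 members, percentile 1.86) had too few members for a ratio. Their secretory product PAEP stood at 21.1 and 1.56 TPM and CXCL14 at 20.2 and 13.5. SCGB1D2, at 10.1 and 9.24 TPM, hardly differed (count fold 1.08, 0.687 to 1.66). Erythroid genes (2.44 TPM, percentile 17) had a median log2 ratio of -0.78, with 7 of 7 lower, but no longer stood apart against a wider central range (percentile 0.115). Haemoglobin took 0.214% of TPM in replicate 1 and 0.126% in replicate 2, HBA1 stood at 1433 and 836 TPM and the embryonic HBE1 at 527 and 343.

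Immediate early and heat shock genes, which respond within minutes to stress, had a median log2 ratio of -1.39, with 10 of 10 lower in replicate 2 and 6 at least 2-fold. Their level of 33.7 TPM lay at percentile 99.8 with both libraries but inside the central 99% without replicate 1 (96.44), against genes of at least 1 TPM (99.17) and with TMM-normalised CPM (99.46). FOS stood at 172 and 66.7 TPM, EGR1 at 33.9 and 3.92, DUSP1 at 206 and 144, ATF3 at 128 and 108 and DNAJB1 at 102 and 74.8. Inflammation and labour genes had a median of -0.56, with 13 of 13 lower, and the neutrophil chemokine CXCL8 stood at 132 and 9.98 TPM. The other lists apart had smaller medians. The insulin-like growth factor list lay at -0.58 with 12 of 15 lower, and macrophages at -0.50 with 11 of 16, where F13A1 stood at 41.8 and 25.4 TPM. Fusion and retroelement genes lay at -0.46 with 11 of 15 lower and cytotrophoblast markers at -0.35 with 10 of 15. Of the latter, only ITGA6 was at least 2-fold lower, at 80.6 and 30.6 TPM. The most abundant of them, KRT18, stood at 289 and 278 TPM. Immune tolerance lay at -0.32 with 13 of 17 lower. The cytotrophoblast list no longer stood apart with a pseudocount of 0.1 (-0.35), among genes of at least 5 TPM (-0.32) or against a wider central range (percentile 0.47). Immune tolerance no longer did so with a pseudocount of 0.1 (-0.34), TMM-normalised CPM (-0.27) or CPM by DESeq2's size factors (-0.27). The same held for genes of at least 5 TPM (-0.31) and for the wider central range (percentile 0.33).

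The remaining 17 lists did not stand apart. Their median log2 ratios were 0.09 for hormones, 0.01 for syncytiotrophoblast, -0.04 for extravillous markers, 0.07 for trophoblast transcription factors and 0.03 for imprinted genes. They were -0.24 for the CRH axis, -0.31 for angiogenic genes, -0.18 for transporters, -0.18 for fetal endothelium and -0.16 for stromal fibroblasts, although POSTN stood at 311 and 8.44 TPM. They were 0.04 for smooth muscle, 0.29 for amnion, -0.28 for hypoxia, -0.17 for interferon, 0.03 for proliferation, 0.17 for mitochondrial genes and -0.11 for ribosomal proteins. The signs for syncytiotrophoblast, extravillous markers, imprinted genes, smooth muscle and proliferation, all close to 0, turned under another filter, scaling or choice of members. None of the 4 X-inactivation transcripts had a row under its symbol.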

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

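The alternatives with 50 reads, 200 bases, posterior mean TPM, a background of all named genes, members of several lists left out and a wider central range were chosen after the data were seen. Pearson's r of 0.954 between the libraries moved to 0.931 and 0.905 with pseudocounts of 0.1 and 0.01, to 0.892 among genes of at least 1 TPM, and to 0.981 with TMM-normalised CPM and 0.981 with CPM by DESeq2's size factors. The coefficient of variation of 0.248 moved to 0.316 with no filter and to 0.278 with DESeq2. The 15125 genes detected became 9756 at 5 TPM. The share of the top 10 genes, 38.9%, moved to 22.3% of counts and to 42.0% without mitochondrial genes. The 833 genes differing 2-fold became 475 with TMM-normalised CPM, 479 with CPM by DESeq2's size factors, 2095 at 1 TPM, 2524 with no filter, 255 at 20 TPM, 471 with 50 reads and 499 with 200 bases, and 705 with posterior mean TPM. A stricter or looser minimum changes how many genes are counted, and the cause of the other shifts was not tested. Leaving out a library gave 16287 to 16721 genes detected, 37.7% to 40.3% for the top 10 and 10 to 13 lists above random lists (14 with both, 12 with TMM-normalised CPM, 10 against genes of at least 1 TPM). Between 7 and 11 lists stood apart (10 in the main setting). Cytotrophoblast, immune tolerance and erythroid lists were lost in some settings, while fetal endothelium (-0.39 at 5 TPM) and hypoxia (-0.41 without shared members) were gained. The loss of the erythroid list against the wider central range turned on the draw of random lists. No list that stood apart changed direction. The medians of 5 lists close to 0 that did not stand apart did so, proliferation with CPM scaled by TMM or DESeq2 and syncytiotrophoblast, extravillous, imprinted and smooth muscle genes with another filter or choice of members. Of the genes differing 2-fold, 418 were higher in replicate 1 and 415 in replicate 2. With TMM-normalised CPM, which changes the unit as well as the scaling, the lean to replicate 1 was stronger, at 278 and 197. In TPM it turned to 980 and 1115 at 1 TPM and to 1097 and 1427 with no filter. FPKM and rescaling without mitochondrial genes multiply the genes of a library by a single factor, so that 65 of 406 gene levels moved beyond the SD marks genes with a small SD and says nothing of their stability. Leaving out 1 of 2 libraries cannot move a mean beyond their SD. No paired analysis was possible because there is 1 group. Depth limits genes with few reads, above all in replicate 1.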

Other observations

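The depth, short-transcript and shared-read tests below were chosen only after the results were seen, and the genes in the next paragraph were picked by rank after their values were seen. All patterns were found and tested on the same 2 libraries.

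Several abundant genes belong to none of the fixed lists. SAT1, the rate-limiting enzyme of polyamine breakdown, stood at 3442 ± 810 TPM (SD, n = 2), the decoy receptor IL13RA2 at 1862 ± 497 and the leptin receptor LEPR at 1806 ± 383, although leptin itself (LEP) stood at 0.56 and 0.91 TPM in the libraries. NOTUM, an extracellular inhibitor of Wnt proteins, reached 1643 ± 360 and the antimicrobial peptide DEFB1 1569 ± 171. The secreted ISM2 reached 1332 ± 137 and the transporter-family members SLC43A3 and SLC7A4 2006 ± 575 and 1186 ± 481. The classical MHC class I gene MAMU-A stood at 1241 ± 386. A gene whose symbol is given as AG stood at 1135 ± 209, and it was not matched to MAMU-AG.

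Among genes with a symbol and at least 50 reads, the largest excess in replicate 2 was that of the phospholipase gene PLA2G2F, with 2 and 58 reads and a count fold of 16.0 (95% interval 4.23 to 135). The calcium channel subunit CACNA2D2 was 8.42-fold higher (5.62 to 13.2), C1RL 7.99-fold (6.12 to 10.6), the receptor MRGPRG 6.77-fold (3.93 to 12.7) and the adenosine receptor ADORA2B 5.92-fold (4.26 to 8.45). OPLAH, an enzyme of glutathione metabolism, was 4.21-fold higher (3.67 to 4.84) and the sodium pump subunit ATP1B1, at 50.8 and 192 TPM, 4.08-fold (3.71 to 4.5). In replicate 1, the chemokine CCL23 was 61.3-fold higher (47.5 to 80.4).

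Decidual stroma and lymphocyte genes were higher in replicate 1, and the labels name no difference between the libraries that bears on it. When replicate 2 was thinned to the depth of replicate 1, the 22 genes of both fixed lists had a median log2 ratio of -1.37. It ranged from -1.49 to -1.24 in 100 draws and was -1.39 before. Thinning keeps each gene's expected TPM, so it tests only sampling noise at the lower depth and cannot decide on depth otherwise. Blood as the only source is argued against only as far as the 7 granulocyte and platelet genes at 1 TPM or more report blood. Their median was only -0.20 (quartiles -0.38 and -0.12), led by CAMP at 52.6 and 29.7 TPM and SELP at 32.6 and 27.1. Whether resident cells express them was not tested, and S100A12, MPO, AQP9 and MMP8 of that list held no read in either library. Some added blood stays open, since erythroid genes had a median of -0.78 (7 of 7 lower in replicate 2) and haemoglobin took 0.214% and 0.126% of TPM. In addition, S100A9 stood at 41.4 and 14.6 TPM and IGKC held 254 and 1 reads. What also stays open as a hypothesis is that replicate 1 may hold more decidua with its NK cells: 11 further decidual stroma genes had a median of -1.91, with TIMP3 at 1698 and 404 TPM and DKK1 at 40.4 and 3.27, and 10 further NK-cell genes a median of -2.22, with FCER1G at 69.1 and 51.9 TPM and PRF1 at 12.1 and 0.41, both below all matched random lists (percentile 0). None (0) of these genes is in a fixed list, but PLA2G2A, at 382 and 442 TPM, and the NK-cell gene XCL1, at 4.13 and 4.92, went the other way, and placental cells express some of them too.

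Small RNAs were frequent among the genes differing 2-fold. Transcripts under 200 bases made up 40.1% of the 833 such genes and 5.17% of the 9882 others. Of the short ones, 98.2% had under 50 reads in sum, as had 91.2% of the short ones among the others. A candidate explanation is therefore counting noise of few reads over a short effective length, and no biological explanation was tested.

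A set of 18 genes had under 1 read in replicate 1 and at least 100 in replicate 2, and none had a symbol. In all 18 the posterior standard deviation of the count exceeded its square root, against 3.63% of 7719 other genes with 100 to 1000 reads, which is consistent with reads shared between near-identical copies, while of 5 genes in the reverse case (at least 100 reads in replicate 1, under 1 in replicate 2) only 2 did. Of the 18, 6 had a length of 3828 bases, as have 56 genes in all. Summed over these 56, the TPM was 189 in replicate 1 and 436 in replicate 2. Equal length alone does not show that they share reads, so this sum cannot decide on reassigned reads, and its difference stays open. An animal's own variants or copy numbers were not tested.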
